A study of Saccharomyces cerevisiae with 21 samples.

How the data were processed

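Poly(A) RNA of budding yeast strain BY4742 was measured by strand-specific RNA sequencing in 21 libraries: 12 from whole cells (3 strains, unstressed or starved of glucose for 24 h, n = 2 in each of 6 groups) and 9 from nuclear extracts of starved cells (3 strains, n = 3). Cells grew in synthetic medium with 2% glucose, and starved cells were washed 3 times into medium without glucose. RNA was selected with oligo(dT) of 25 nt, so RNA without a poly(A) tail is largely lost before counting. Nuclear extracts were made from spheroplasts by breaking the cells and spinning them on a sucrose gradient.

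The deposited values are counts, as raw read counts per gene with no normalization, and were read as such: no count in any file was other than a whole number (0 such values). Per the file headers the authors counted with featureCounts 2.0.1, per gene feature, reverse-stranded, with multi-mapping reads allowed as fractions and reads that overlap several genes left out; the values are whole although fractions were allowed. Per the labels the authors trimmed adapters with cutadapt and aligned with TopHat2, whose versions are not given in the sources used here. The whole cell files name annotation release R64-2-1, with 6600 yeast features. The nuclear files hold the same 6600 features and 6 spike-in sequences, of which 4 have reads. The reference used here, assembly R64 of strain S288C with annotation R64-5-1, matched 5917 of the features by locus name, 5888 with the same start and end and 29 with others, and 683 were not matched; positions are those of the count files.

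Depth was 4815254 to 14069868 counts in whole cell libraries and 6353585 to 23138938 in 7 nuclear libraries. Nuclear wild type replicate 3 (1079 counts) and interface mutant replicate 3 (3981 counts) lie under 0.2 of the nuclear median of 8719732. Shares of counts are given with the SD between libraries, and where a share was 0 the limit is that of 3 counts; such limits and exact (Clopper-Pearson, 95%) intervals cover counting error only, since reads are not independent molecules.

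Groups were taken from the labels alone. Each fit used edgeR 4.0.16 (R 4.3.3) with TMM factors, genes kept by filterByExpr (minimum count 10), the quasi-likelihood F test, and Benjamini-Hochberg adjustment with a threshold of 0.05. There were 15 planned comparisons in 3 fits: whole cell libraries (5853 genes), nuclear libraries (5902 genes) and starved libraries of both fractions (5936 genes). A comparison of both nuclear mutants together against wild type was added after seeing the data. Where 1 library was left out of a group of 2, the lone library was assumed to vary like the other groups. Differences between strains in the starvation response or in the distribution between fractions were tested as interaction terms. Shares of counts were compared by 2-sided exact permutation tests. RNA levels are relative to all counted RNA of a library; a change in total RNA per cell is not seen.

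Gene lists were fixed before the data were examined: cytosolic ribosomal proteins, ribosome biogenesis, Hsf1-type chaperones, Msn2/4-type general stress genes, trehalose and glycogen metabolism, high- and low-affinity hexose transport, glycolysis and fermentation, gluconeogenesis with the glyoxylate cycle and acetate use, the TCA cycle, the respiratory chain, peroxisomal fatty acid oxidation, autophagy, the proteasome, histones, cyclins and DNA replication, amino acid biosynthesis, mRNA export and poly(A) binding, nuclear exosome and surveillance (22 of 23 names found), cell wall integrity, mitochondrial genome transcripts and intron-containing genes other than ribosomal protein genes. Marker genes deleted in the parent and mating-type genes served as strain checks. Small nuclear and nucleolar RNA have no feature of their own in the files (0 members) and were not analysed here. Each of 22 lists was tested in each of 15 comparisons (330 tests) with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison; camera with an estimated correlation and fry were the alternatives. In the tests that passed, median, mean and test direction had the same sign. Calls within a list are given over all genes and adjusted over the list alone.

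The genes named were chosen by a rule set before the data were examined: NAB2 and the deleted markers; the 8 largest rises and 8 largest falls among nuclear protein-coding genes past the threshold with at least 10 CPM in a compared group and no overlap between the groups' libraries (for interactions without the overlap rule); up to 3 members of each list with the smallest adjusted p among those past the threshold; and where fewer than 5 genes passed, all of these and the 3 smallest p values. The text prints part of these, and 1 gene is not reported here. Features that overlap small nucleolar RNA genes and the mating-type genes with values were singled out after their values were seen.

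The alternatives set before the data were examined were median-of-ratios factors, DESeq2 1.42.0, no filter, a filter at a mean of 10 CPM, the replicate number as a block, the compared groups alone, protein-coding genes alone, each library left out in turn, and for nuclear libraries limma's voom with sample weights, a fit without the 2 shallow libraries and 1 fit of all libraries. Spike-in factors, fits without the nuclear mutant libraries that lay nearer the other mutant, list tests without unstressed wild type replicate 1 or without the shallow libraries, and combinations with the depth limit were chosen after seeing the data. The methods were tested on simulated data in which 200 genes were changed 2-fold or 4-fold: of 100 genes changed 4-fold, 92 were called for the starved IDR mutant against wild type (2.68% false calls) and 94 for the nuclear IDR mutant (20.7% false calls). Sharing of wild type libraries by both mutants was tested with 30 simulations of no effect. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.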

Results

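Poly(A) RNA of budding yeast was sequenced in 21 libraries, of which 12 came from whole cells and 9 from nuclear extracts. The strains carried NAB2, the gene of a nuclear poly(A) RNA-binding protein, with a green fluorescent protein tag at its own locus. They were a tagged wild type, an "IDR mutant" that lacks residues 104 to 263 and carries a viral nuclear localization signal, and an "interface mutant" with a substitution at residue 450. Whole cell libraries covered the 3 strains in glucose medium (unstressed) and after 24 h without glucose (starved), with n = 2 in each of 6 groups. Nuclear extract libraries covered the starved strains only, with n = 3 in each of 3 groups. The whole cell libraries held 4815254 to 14069868 counts in yeast genes. Of the nuclear libraries, 7 held 6353585 to 23138938 counts, wild type replicate 3 held 1079 and interface mutant replicate 3 held 3981. Changes are log2 fold changes ± standard error (SE) from edgeR, and a gene rose or fell where its adjusted p was under 0.05. Whether replicates were separate cultures is not stated, so the tests measure only the spread between these libraries, which may be technical.

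NAB2 (YGL122C, chromosome VII, 278946 to 280523) was compared first, as the targeted gene. In whole cells it stood at 49.8 and 201.3 CPM (counts scaled by library size) in unstressed wild type, 205.4 and 225.5 in the unstressed IDR mutant, and 253.6 and 208.3 in the unstressed interface mutant. After starvation it stood at 370.4 and 380 CPM in wild type, 133 and 123.2 in the IDR mutant, and 234.5 and 356.5 in the interface mutant. In nuclear extracts it stood at 414.4, 431.3 and 0 CPM in wild type replicates 1 to 3, and at 277.4, 296.5 and 127.3 in the libraries labelled IDR mutant. It stood at 119.1, 330.6 and 251.2 in those labelled interface mutant, where the last value rests on 1 count. NAB2 rose with starvation in wild type (1.70 ± 0.40, adjusted p = 0.00422). The rise was 1.14 ± 0.22 without unstressed replicate 1 and 2.62 ± 0.24 without unstressed replicate 2. NAB2 stood at -0.35 ± 0.39 in the IDR mutant (adjusted p = 0.44) and 0.72 ± 0.39 in the interface mutant (adjusted p = 0.137). It was lower in the starved IDR mutant than in starved wild type (-1.37 ± 0.39, adjusted p = 0.0278), a call it lost without any 1 of the 4 libraries compared. The deletion takes 160 of 525 residues (30.5%) out of the counted feature, which can by itself lower NAB2 counts in the IDR mutant against wild type. It was present in both conditions, but before starvation NAB2 was not lower in the IDR mutant than in wild type (0.68 ± 0.39, adjusted p = 0.219). Without unstressed wild type replicate 1 that difference was 0.12. A single substitution leaves the feature whole, so the level of NAB2 checks the strain labels only weakly. LEU2, LYS2 and URA3, which the parent strain lacks, had at most 5 counts in any library, while HIS3 had 43 to 752 in the libraries with enough depth. The alpha-factor gene MF(ALPHA)1 had counts in each of these libraries, as an alpha strain should.

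**Figure D1:**
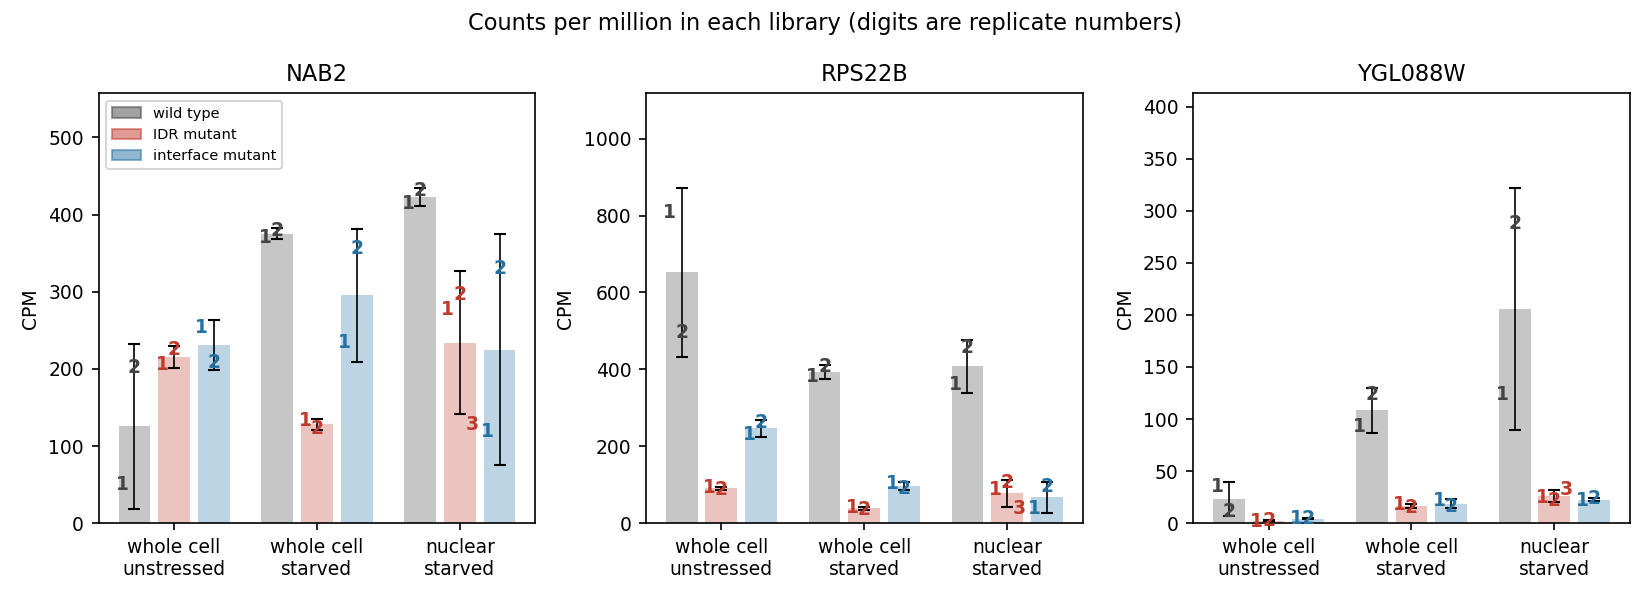
CPM (y axis) of NAB2, RPS22B and YGL088W in whole cell and nuclear extract libraries by strain. Bars are group means, error bars are the SD, and digits mark replicates. The 2 shallow nuclear libraries, with 1079 and 3981 counts, are not drawn. NAB2 stands at 49.8 in unstressed wild type replicate 1 against 201.3 in replicate 2. RPS22B and YGL088W stand lower in both mutants than in wild type in each group of libraries drawn.

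Some libraries stood apart from the rest of their group. Unstressed wild type replicate 1 had a median Spearman correlation over genes of 0.848 with the other unstressed libraries, where the other 5 had 0.98 to 0.988. Ribosomal protein genes took 34% of its counts against 21.1% in replicate 2. Starved interface mutant replicate 1 correlated at 0.976 with each starved wild type library and at 0.955 with its own replicate 2. The counts of that pair differed with a chi-square of 43.9 per degree of freedom, against 3.03 and 6.33 in the starved wild type and IDR mutant pairs. In the nuclear extracts, the labels of the mutants were checked with 114 genes that part the mutants in starved whole cells (96 higher and 18 lower in the IDR mutant). The mean score over these genes was 1.99 in the starved whole cell IDR mutant and -0.08 in the starved whole cell interface mutant. Unstressed whole cells scored -1.52 and -1.59 in the IDR mutant and -3.11 and -3.26 in the interface mutant. Unstressed wild type scored -3.48 and -3.16. In each strain the score rose with starvation by more than the starved mutants differed. The score thus follows starvation as well as strain. The nuclear library labelled interface mutant replicate 1 scored 1.85, and the libraries labelled IDR mutant replicates 1 and 2 scored 0.60 and 0.17, so that 3 of the 5 mutant nuclear libraries with enough depth lay nearer the other mutant. The libraries labelled IDR mutant replicate 3 and interface mutant replicate 2 scored 1.98 and 0.70. Wild type scored 0.03 and 0.40 in nuclear replicates 1 and 2 and -0.53 and -0.56 in starved whole cells, so in wild type the score is higher in nuclear extracts, and IDR mutant replicates 1 and 2 lie near nuclear wild type as well. Taken relative to the wild type of each fraction, a check added after seeing the data, the same 3 libraries lay nearer the other mutant. These labels were kept, and each direction in nuclear mutants below is that of the library labels.

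**Figure D2:**
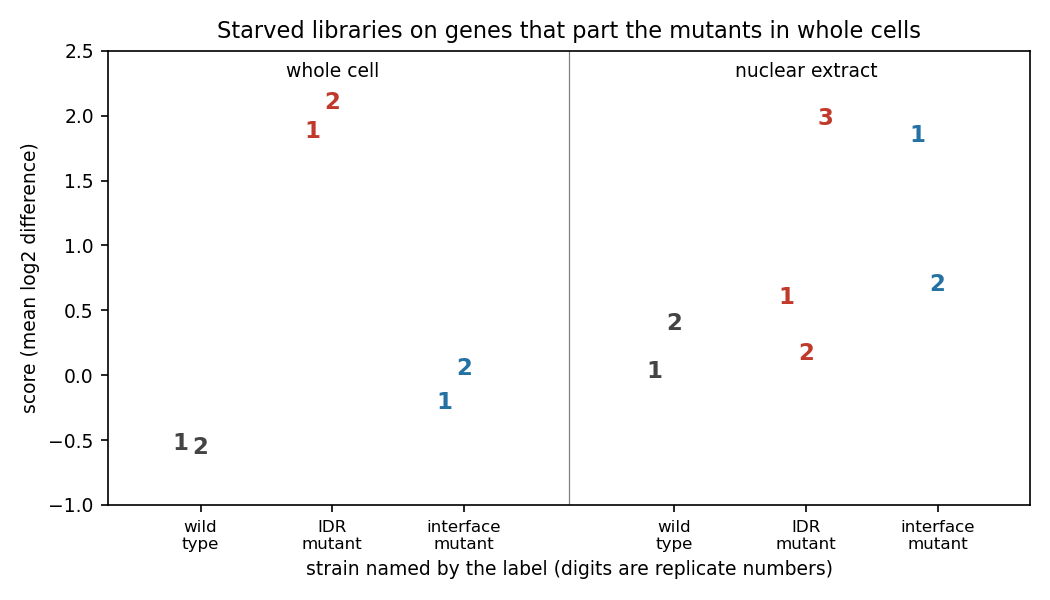
Score of each starved library (y axis, mean log2 difference over genes that part the 2 mutants in both starved and unstressed whole cells) by the strain its label names, for whole cells and nuclear extracts. Digits mark replicates. The library labelled interface mutant replicate 1 scores 1.85 and those labelled IDR mutant replicates 1 and 2 score 0.60 and 0.17, where the whole cell means are 1.99 for the IDR mutant and -0.08 for the interface mutant.

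The first comparison asked how starvation changes the RNA of wild type whole cells (n = 2 in each condition). Heat shock genes were among those that rose most: HSP30, which encodes a plasma membrane stress protein, rose 301-fold (8.23 ± 0.25, adjusted p = 7.54e-08). SSA4, an inducible Hsp70, rose 158-fold (7.30 ± 0.21, adjusted p = 5.74e-08), and HSP104, a disaggregase, rose by 4.69 ± 0.16. YNL194C, of a family of plasma membrane proteins, rose by 9.09 ± 0.30, and CTA1, the peroxisomal catalase, by 8.25 ± 0.32. Among the genes that fell were the ribosomal protein gene RPS4B (-3.08 ± 0.16), the G1 cyclin gene PCL1 (-4.20 ± 0.21), ASF1, which encodes a histone chaperone (-4.67 ± 0.43), and the pheromone-regulated gene PRM6 (-4.90 ± 0.43). Of 5853 genes tested, 1855 rose and 2021 fell.

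Stress and storage genes rose together in starved wild type. Of 22 chaperone genes of the Hsf1 type, 18 rose and 4 did not pass, both over all genes and adjusted over the list alone (camera adjusted p = 9e-09, and adjusted p = 0.0275 with an estimated correlation). HSP78, a mitochondrial chaperone, rose by 3.85 ± 0.13. Of 32 general stress genes of the Msn2/4 type, 29 rose, in both counts (camera adjusted p = 1.03e-11, adjusted p = 0.0968 with an estimated correlation). DDR2 stood at 6.58 ± 0.21, the small heat shock gene HSP26 at 5.99 ± 0.20 and the cell wall gene SPI1 at 5.98 ± 0.27. Of 14 trehalose and glycogen genes, 13 rose, in both counts (camera adjusted p = 2.02e-07, adjusted p = 0.359 with an estimated correlation). The glycogen genes GLC3 and GSY2 stood at 5.17 ± 0.22 and 3.02 ± 0.14. Of 24 autophagy genes, 13 rose and 3 fell, in both counts (camera adjusted p = 0.00704, adjusted p = 0.107 with an estimated correlation). ATG8 stood at 3.93 ± 0.22 and ATG1 at 5.25 ± 0.33. Of 20 cell wall integrity genes, 10 rose and 3 fell, in both counts (camera adjusted p = 0.0384, adjusted p = 0.651 with an estimated correlation). Without unstressed wild type replicate 1 the cell wall list did not pass (camera adjusted p = 0.0926), and chaperones of the Hsf1 type had adjusted p = 0.119 with an estimated correlation.

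Genes for the use of other carbon sources rose as well. All 7 genes of high-affinity hexose transport and sucrose use rose, in both counts (camera adjusted p = 6.97e-06, adjusted p = 0.127 with an estimated correlation). The near-identical HXT6 and HXT7, whose reads counting may have split, stood at 5.27 ± 0.16 and 4.26 ± 0.16. Of 16 genes of gluconeogenesis, the glyoxylate cycle and acetate use, 15 rose, and all 16 did adjusted over the list alone (camera adjusted p = 5.8e-08, adjusted p = 0.131 with an estimated correlation). ADY2, an acetate permease, rose by 7.19 ± 0.20, CAT8, a transcription activator of this group, by 5.23 ± 0.24, and ICL1, isocitrate lyase, by 3.10 ± 0.16. All 16 genes of peroxisomal fatty acid oxidation rose, in both counts (camera adjusted p = 5.63e-08, adjusted p = 0.107 with an estimated correlation). The thiolase gene POT1 stood at 6.21 ± 0.27. Of 17 glycolysis and fermentation genes, 11 rose and 2 fell, and of 32 nuclear genes of the respiratory chain 13 rose and 2 fell, each in both counts (camera adjusted p = 0.0161 for each list, adjusted p = 0.554 for each with an estimated correlation). The TCA cycle (6 of 14 rose, 1 fell, camera adjusted p = 0.0928), mitochondrial genome transcripts (3 of 8 rose, camera adjusted p = 0.111) and the low-affinity hexose transporters (1 rose and 1 fell, camera adjusted p = 0.936) did not pass as lists.

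Ribosomal protein genes fell in starved wild type. Of 138 cytosolic ribosomal protein genes, 126 fell and none rose, and 128 fell adjusted over the list alone (camera adjusted p = 2.84e-20, adjusted p = 0.282 with an estimated correlation). RPL8A stood at -2.19 ± 0.14. Reads of paralog pairs may be split in these counts. The share of all counts in this list was 6.31% ± 0.173 (SD, n = 2) after starvation. Of 50 ribosome biogenesis genes, 31 fell and 4 rose, in both counts (camera adjusted p = 4.4e-05, adjusted p = 0.472 with an estimated correlation). BRX1 stood at -2.05 ± 0.13 and SOF1 at -2.39 ± 0.17. Of 22 nuclear exosome and surveillance genes, 14 fell and 3 rose (camera adjusted p = 0.0161, adjusted p = 0.141 with an estimated correlation). The exosome core gene RRP40 stood at -1.74 ± 0.15. Of 24 cyclin and DNA replication genes, 12 fell and 3 rose (camera adjusted p = 0.0355, adjusted p = 0.554 with an estimated correlation). The mitotic cyclins CLB1 and CLB2 stood at -3.63 ± 0.26 and -2.31 ± 0.21. The 30 genes of mRNA export and poly(A) binding went both ways, with 9 up and 10 down (camera adjusted p = 0.936, median 0.00, mean 0.03). MEX67, the export receptor, rose by 2.37 ± 0.19 and SUB2, an export helicase, fell (-2.10 ± 0.22). Histones (0 of 10 up, 5 down, camera adjusted p = 0.117), amino acid biosynthesis (15 of 34 up, 10 down, camera adjusted p = 0.206), the proteasome (8 of 33 up, 11 down, camera adjusted p = 0.376) and intron-containing genes other than ribosomal protein genes (51 of 175 up, 62 down, camera adjusted p = 0.872, median -0.06 and mean 0.01) did not pass. The number of genes called was 4555 without unstressed wild type replicate 2 and 3136 without starved wild type replicate 1, and the compared groups alone gave 2473. All 32 of the called genes named here for wild type passed with each library left out in turn.

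**Figure D3:**
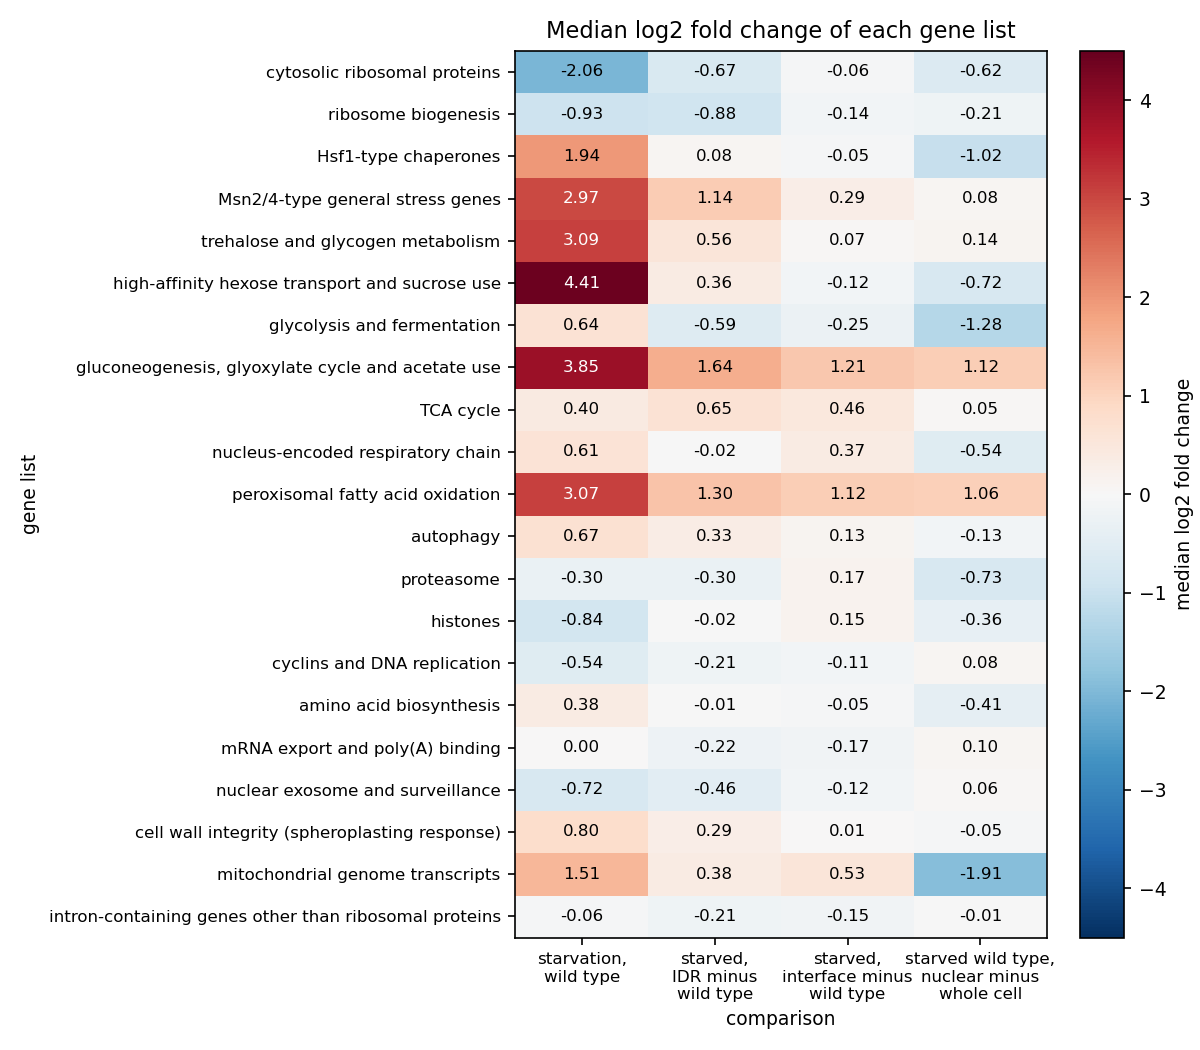
Median log2 fold change (color and printed value) of each gene list (y axis) in 4 comparisons (x axis): starvation in wild type whole cells, each mutant against wild type in starved whole cells, and nuclear extract against whole cell in starved wild type. The 2-member list of low-affinity hexose transporters is not drawn. The medians of gluconeogenesis and of peroxisomal fatty acid oxidation lie above 1 in all 4 columns, and that of ribosomal protein genes lies at -2.06, -0.67, -0.06 and -0.62.

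The starvation response was measured in each mutant in the same way (n = 2 in each condition). In the IDR mutant ADY2 rose by 9.52 ± 0.22 (adjusted p = 2.21e-08), MLS1, malate synthase, by 7.81 ± 0.27, AUA1 by 10.22 ± 0.89 and SSA4 by 6.60 ± 0.20. The ribosome biogenesis genes MAK16 and BRX1 fell (-3.94 ± 0.56 and -2.90 ± 0.13), as did RPS4B (-3.19 ± 0.16). In the interface mutant HSP30 rose by 9.94 ± 0.27, ADY2 by 9.69 ± 0.23 and SSA4 by 8.47 ± 0.22. Falls were seen for ASF1 (-6.20 ± 0.47), the ribosomal RNA processing gene RRP14 (-5.04 ± 0.59) and RPS4B (-3.50 ± 0.17). In the IDR mutant 132 of 138 ribosomal protein genes and 48 of 50 ribosome biogenesis genes fell, and all 32 Msn2/4-type genes, 16 genes of gluconeogenesis and 16 of peroxisomal fatty acid oxidation rose, in both counts. In the interface mutant 113 ribosomal protein genes and 35 biogenesis genes fell (115 and 36 adjusted over the list alone), and 30 Msn2/4-type genes, all 16 genes of gluconeogenesis and all 16 of peroxisomal fatty acid oxidation rose, in both counts. With an estimated correlation the Msn2/4-type list kept its call in the mutants (adjusted p = 0.0461 in the IDR mutant and 0.0435 in the interface mutant), and the ribosomal protein list did not (adjusted p = 0.224 and 0.282). The edgeR test called 3941 genes in the IDR mutant (1932 up, 2009 down) and 3510 in the interface mutant (1739 up, 1771 down), and 1298 genes rose and 1330 fell in all 3 strains. Of the genes called in wild type, 1456 also rose and 1578 also fell in the IDR mutant, where unrelated calls would share 612 and 694, and 50 moved in opposite ways. The interface mutant shared 1427 rises and 1444 falls with wild type (551 and 612 by chance), with 2 in opposite ways.

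Before starvation, the IDR mutant was compared with wild type to ask what the deletion changes in growing cells (n = 2 each). Stress and glucose transport genes were higher in the mutant: the stress gene DDR2 rose by 2.27 ± 0.19 (adjusted p = 0.00311), and GPH1, glycogen phosphorylase, by 1.83 ± 0.24. HSP26 rose by 1.20 ± 0.16, HXT4 by 1.61 ± 0.23, and HXT6 and HXT7 by 1.54 ± 0.14 and 1.46 ± 0.14. The mating adhesin genes FIG2 and AGA1 (2.33 ± 0.35 and 1.94 ± 0.38) and NCA3 (2.53 ± 0.43) rose too. RPS22B (YLR367W), a ribosomal protein gene with a small nucleolar RNA in its intron, fell (-3.19 ± 0.35, adjusted p = 0.00502). So did YGL088W (-3.78 ± 0.64), SPO1 (-3.02 ± 0.35), the proton pump gene VMA9 (-1.15 ± 0.14), RPS14B (-0.99 ± 0.15) and the histone chaperone gene VPS75 (-0.98 ± 0.15). As lists, 10 of 32 Msn2/4-type genes rose (18 rose and 2 fell adjusted over the list alone, camera adjusted p = 3.32e-07), and 2 of 14 trehalose and glycogen genes did (13 alone, camera adjusted p = 2.48e-06). So did 3 of 7 high-affinity hexose genes (7 alone, camera adjusted p = 4.42e-06) and 2 of 20 cell wall genes (9 up and 1 down alone, camera adjusted p = 3.89e-05). Ribosomal protein genes (4 of 138 fell in both counts, median -0.54, camera adjusted p = 8.46e-06) and other intron-containing genes (4 of 175 fell, 6 up and 49 down alone, median -0.35, camera adjusted p = 9.63e-05) passed downward. With an estimated correlation none of these lists passed (adjusted p = 0.257 for Msn2/4-type and high-affinity hexose genes, 0.545 for intron-containing genes, and 0.68 for the others). Wild type replicate 1 moves with these lists. Its median log2 ratio of CPM to replicate 2 was -0.71 for Msn2/4-type, -1.03 for trehalose and glycogen and -1.1 for high-affinity hexose genes. It was -1.22 for cell wall, -0.21 for intron-containing and 0.45 for ribosomal protein genes. The TMM factors of the fit (0.799 for replicate 1, 1.163 for replicate 2) would raise each of these ratios by the same amount. Without wild type replicate 1 the ribosomal protein list did not pass (camera adjusted p = 0.457), and the others did (9.79e-14, 2.19e-06, 1.5e-06, 0.000484 and 1.5e-06 in that order). In all, edgeR called 98 of 5853 genes (66 up, 32 down), and DESeq2 called 1352 with more falls than rises (513 up, 839 down). The compared groups alone gave 0. Each of the called genes named here lost its call with some library left out. The count was 3807 without wild type replicate 2, 0 without IDR mutant replicate 1, and 2 without IDR mutant replicate 2.

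The unstressed interface mutant gave no called gene against unstressed wild type by edgeR (n = 2 each, 0 of 5853), with 1422 genes at an unadjusted p under 0.05 and 100 called by DESeq2 (2 up, 98 down). The smallest p values belonged to VMA9 (-1.09 ± 0.14, adjusted p = 0.165), YJL047C-A (-1.99 ± 0.34, adjusted p = 0.196) and THP3 (-0.88 ± 0.16, adjusted p = 0.196). The ribosomal protein list passed downward (0 of 138 genes called in either count, median -0.61, camera adjusted p = 9.94e-08), and had adjusted p = 0.623 with an estimated correlation. The list stood higher in wild type replicate 1 than in replicate 2 (median log2 ratio 0.45), and without replicate 1 it had camera adjusted p = 0.0128. Without unstressed wild type replicate 2, which leaves replicate 1 alone in its group, edgeR called 3655 genes.

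After starvation, the IDR mutant differed from wild type in 1710 of 5853 genes (n = 2 each, 930 up, 780 down). Genes for the use of acetate and fatty acids were higher: ADY2 rose by 2.42 ± 0.16 (adjusted p = 7.67e-05), ACS1, acetyl-CoA synthetase, by 2.36 ± 0.25 and ICL1 by 1.63 ± 0.15. The carnitine acetyltransferase genes YAT1, YAT2 and CAT2 rose by 3.56 ± 0.40, 2.89 ± 0.30 and 2.11 ± 0.20. FDH1, formate dehydrogenase, which has a near-identical copy, rose by 4.41 ± 0.28, PDC6, a minor pyruvate decarboxylase, by 4.01 ± 0.39, and FMP45 by 3.42 ± 0.22. RPS22B fell as before starvation (-3.19 ± 0.35, adjusted p = 0.000442), as did YGL088W (-2.55 ± 0.56) and the proton pump gene VMA9 (-1.43 ± 0.15). RPA190, the largest subunit of RNA polymerase I, fell too (-1.35 ± 0.12).

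By list, 15 of 16 genes of gluconeogenesis, the glyoxylate cycle and acetate use rose in the starved IDR mutant (16 adjusted over the list alone, camera adjusted p = 7.55e-11, adjusted p = 0.139 with an estimated correlation). Of 16 genes of peroxisomal fatty acid oxidation 14 rose (16 alone, camera adjusted p = 2.48e-11, adjusted p = 0.0929 with an estimated correlation). The carnitine carrier CRC1 stood at 2.22 ± 0.20. Of 32 Msn2/4-type genes 22 rose (27 alone, camera adjusted p = 4.47e-12, adjusted p = 0.0929 with an estimated correlation). PHM7 stood at 2.55 ± 0.16, TFS1 at 1.79 ± 0.15 and the aldehyde dehydrogenase ALD3 at 1.97 ± 0.17. Of 14 TCA cycle genes 7 rose (10 alone, camera adjusted p = 0.000328, adjusted p = 0.425 with an estimated correlation). Citrate synthase CIT1 stood at 0.89 ± 0.12. Trehalose and glycogen genes (5 of 14 up, 9 alone, camera adjusted p = 0.000665, adjusted p = 0.453 with an estimated correlation) and high-affinity hexose genes (3 of 7 up in both counts, camera adjusted p = 0.0132, adjusted p = 0.425 with an estimated correlation) passed upward. Ribosome biogenesis genes fell in 29 of 50 cases and rose in 1 (36 and 2 alone, camera adjusted p = 2.93e-11, adjusted p = 0.255 with an estimated correlation). The polymerase I subunit RPA43 stood at -1.25 ± 0.14. Ribosomal protein genes fell in 45 of 138 cases (46 alone, median -0.67, camera adjusted p = 4.03e-13, adjusted p = 0.425 with an estimated correlation). RPL16A stood at -1.52 ± 0.14 and RPL36B at -1.20 ± 0.12. The share of counts in this list was 3.93% ± 0.0327 (SD, n = 2) in the IDR mutant against 6.31% ± 0.173 in wild type.

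Some genes of nuclear RNA handling fell in the starved IDR mutant. Of 22 nuclear exosome and surveillance genes 5 fell and 1 rose (6 and 1 alone, camera adjusted p = 0.0132, adjusted p = 0.205 with an estimated correlation). The helicase gene MTR4 stood at -1.14 ± 0.16 and the exosome nuclease gene DIS3 at -0.62 ± 0.13. Of 30 mRNA export and poly(A) binding genes 5 fell and 1 rose, in both counts, where 780 of all 5853 genes fell, and the list did not pass (camera adjusted p = 0.115). The fallers included the export helicase gene DBP5 (-0.98 ± 0.13) and the RNA-binding protein genes HRB1 (-0.96 ± 0.17) and HRP1 (-0.81 ± 0.16). Intron-containing genes other than ribosomal protein genes fell in 38 of 175 cases and rose in 13, in both counts (median -0.21, camera adjusted p = 0.0132, adjusted p = 0.433 with an estimated correlation). The spore wall gene LDS2 stood at 2.45 ± 0.21 and the prefoldin gene GIM5 at -1.24 ± 0.14. Glycolysis (2 of 17 up and 7 down, camera adjusted p = 0.0132) and the proteasome (1 of 33 up and 7 down, camera adjusted p = 0.0132) passed downward and each had adjusted p = 0.453 with an estimated correlation. Of the called genes named for this comparison, NAB2, YGL088W, DIS3 and HRP1 lost their call with some library left out, and the others passed with each left out in turn. The count of called genes was 796 without starved wild type replicate 1, 843 without wild type replicate 2, 991 without IDR mutant replicate 1 and 800 without IDR mutant replicate 2. The compared groups alone gave 3575.

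The starved interface mutant differed from starved wild type in 28 genes (24 up, 4 down, n = 2 each). Genes for the use of other carbon sources were among them: ADY2 rose by 1.81 ± 0.16 (adjusted p = 0.0046) and MLS1 by 1.55 ± 0.19. PCK1, phosphoenolpyruvate carboxykinase, rose by 1.66 ± 0.28, ICL1 by 1.18 ± 0.15, POT1 by 1.60 ± 0.21, CRC1 by 1.49 ± 0.20 and the fatty acid oxidation gene DCI1 by 1.10 ± 0.15. RGI2 (1.80 ± 0.18), ARO10, a decarboxylase of amino acid breakdown (1.70 ± 0.16), the hexose transporter gene HXT5 (1.66 ± 0.26), FDH1 (1.58 ± 0.27), PHM7 (1.44 ± 0.16) and CIT1 (0.89 ± 0.12) rose too. The 4 that fell were YJL047C-A (-2.40 ± 0.29, adjusted p = 0.0122), RPS22B (-1.93 ± 0.33, adjusted p = 0.0489), COS10, of a family of near-identical copies (-1.81 ± 0.27), and MMO1 (-1.77 ± 0.28). Gluconeogenesis (5 of 16 up, 13 adjusted over the list alone, median 1.21, camera adjusted p = 1.96e-21) and peroxisomal fatty acid oxidation (5 of 16 up, 15 alone, median 1.12, camera adjusted p = 9.51e-23) passed with an estimated correlation as well (adjusted p = 0.0399 and 0.0298). The TCA cycle (1 of 14 up, 3 alone, camera adjusted p = 4.12e-08), Msn2/4-type genes (1 of 32 up, 5 alone, camera adjusted p = 2.48e-06) and the respiratory chain (0 of 32 in both counts, camera adjusted p = 0.000147) passed upward with the preset correlation. They had adjusted p = 0.323, 0.261 and 0.425 with an estimated correlation. All 28 genes were also called in the same direction in the starved IDR mutant, where unrelated calls would share 3.81 rises and 0.533 falls. The 2 mutants share the wild type libraries, which alone raises such overlap. Changes correlated over genes at Pearson r = 0.526 (genes are not independent replicates). Data simulated with no effect of either mutant gave 0.517 (0.462 to 0.552). They held too few calls (means of 0.0667 and 0.0333 genes) to show how many shared calls the wild type libraries alone would give. The covariance of the changes was 0.173, against 0.059 in the simulated data. Each of the 17 called genes named here lost its call with some library left out. The edgeR count was 0 without either wild type replicate, 3 without interface mutant replicate 2 and 288 without interface mutant replicate 1, where falls outnumbered rises (80 up, 208 down). DESeq2 called 225 genes (186 up, 39 down), and the compared groups alone gave 46 (40 up, 6 down).

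Whether the starvation response differs between strains was tested by the interaction term (n = 2 in each of 4 groups). In the IDR mutant the rise of MLS1 was larger than in wild type by 3.51 ± 0.34 (adjusted p = 0.00394). So were the rises of ADY2 (2.33 ± 0.24), YAT2 (3.43 ± 0.41), the fatty acyl transporter gene PXA1 (2.62 ± 0.31), the lactate permease gene JEN1 (2.59 ± 0.43), FDH1 (3.94 ± 0.55) and ADH7 (4.03 ± 0.89). The change was more negative than in wild type for RPA190 (-1.48 ± 0.16, adjusted p = 0.00394), RPA43 (-1.24 ± 0.19), the ribosome biogenesis genes NUG1 and UTP6 (-1.42 ± 0.22 and -2.09 ± 0.37), MMO1 (-2.29 ± 0.47), MTR4 (-1.42 ± 0.22), DBP5 (-1.10 ± 0.18) and NAB2 (-2.05 ± 0.55, adjusted p = 0.0454). Without unstressed wild type replicate 1 the NAB2 difference was -1.50 ± 0.28, and without replicate 2 it was -2.98 ± 0.29. Without any 1 of the starved or unstressed IDR mutant or starved wild type libraries it did not pass. The change of the importin gene KAP123 was 4-fold lower (SE 0.32 in log2, adjusted p = 0.00884). Of 50 ribosome biogenesis genes 21 were more negative (27 adjusted over the list alone, median -0.95, camera adjusted p = 1.56e-13). Of genes of gluconeogenesis 10 of 16 (12 alone, camera adjusted p = 3.6e-07) and 9 of 16 of peroxisomal fatty acid oxidation (12 alone, camera adjusted p = 4.53e-08) were more positive. With an estimated correlation these lists had adjusted p = 0.203, 0.203 and 0.18. Ribosomal protein genes were more negative in 16 of 138 cases, in both counts (median -0.10, camera adjusted p = 0.00129, adjusted p = 0.773 with an estimated correlation), and without unstressed wild type replicate 1 camera gave an adjusted p of 2.91e-19 (0.284 with an estimated correlation). Glycolysis (5 of 17 more negative and 1 more positive, 10 and 1 alone, camera adjusted p = 0.000238) and nuclear exosome and surveillance genes (3 of 22 more negative, 5 alone, camera adjusted p = 0.00422) passed too, with adjusted p = 0.454 and 0.18 with an estimated correlation. The edgeR interaction test called 687 genes (365 up, 322 down), DESeq2 called 1192, and the compared groups alone gave 248. It called 1488 and 3209 without unstressed wild type replicates 1 and 2, and 32 and 63 without the starved ones. The count was 104 and 46 without unstressed IDR mutant replicates 1 and 2, and 235 and 76 without the starved ones. Of the 16 called genes named here, 6 passed with each library left out. In the interface mutant 1 gene passed, ADY2, whose rise was 5.66-fold larger than in wild type (SE 0.25 in log2, adjusted p = 0.0162), ahead of MLS1 (2.37 ± 0.32, adjusted p = 0.0698) and YIG1 (1.89 ± 0.27, adjusted p = 0.0698). An unadjusted p under 0.05 was met by 1138 genes, DESeq2 called 156, and the compared groups alone gave 0. The count was 33 and 3274 without unstressed wild type replicates 1 and 2, 171 without starved interface mutant replicate 1, and 0 without any 1 of the other 5 libraries. Of the lists, peroxisomal fatty acid oxidation (0 of 16, 11 alone, median 1.40, camera adjusted p = 3.65e-09) and gluconeogenesis (1 of 16, 12 alone, median 1.61, camera adjusted p = 1.91e-08) were more positive in the interface mutant than in wild type. They had adjusted p = 0.257 and 0.331 with an estimated correlation.

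Nuclear extracts of starved cells were compared between strains to ask which transcripts differ in level there (n = 3 each). This comparison cannot tell a changed distribution between nucleus and cytoplasm from a changed level in the whole cell. YGL088W and RPS22B, named below, also fell in starved whole cells of the IDR mutant, and RPS22B in those of the interface mutant. In the libraries labelled IDR mutant, 1 gene passed against wild type: YGL088W, chromosome VII, 345836 to 346201, which overlaps a small nucleolar RNA gene on its own strand, fell (-2.70 ± 0.34, adjusted p = 0.000734). RPS22B stood at -2.15 ± 0.42 (adjusted p = 0.096) and YHR054C, a copy within a repeated locus, at 1.96 ± 0.36 (adjusted p = 0.0728). In the libraries labelled interface mutant, YGL088W was again the 1 gene that passed, and it fell (-2.88 ± 0.40, adjusted p = 0.00275). RPS22B stood at -2.16 ± 0.49 and JLP1, a sulfonate dioxygenase gene, at 1.60 ± 0.35 (adjusted p = 0.477 for each). For both mutants together, a comparison added after seeing the data, YGL088W (-2.79 ± 0.29, adjusted p = 4.07e-05) and RPS22B (-2.15 ± 0.37, adjusted p = 0.0265) fell and YHR054C stood at 1.75 ± 0.34 (adjusted p = 0.0947). Between the libraries labelled with the 2 mutants edgeR called 0 of 5902 genes. YER053C-A (1.75 ± 0.39), YIL100W (1.16 ± 0.28) and YOR302W (0.94 ± 0.24) had the smallest p values, each with adjusted p = 1. Changes in the 2 nuclear mutants correlated over genes at Pearson r = 0.773, against 0.557 (0.537 to 0.578) in data simulated with no effect of either. These simulated data held on average 5.67 called genes for the IDR mutant and 5.23 for the interface mutant. On average 1.23 genes, and at most 4, were called in both in the same direction. The simulated data thus held more calls than the real comparisons, with 1 call for each label. They cannot tell whether the 1 shared call exceeds what the shared wild type libraries alone would give. DESeq2 called 0 genes in each of these comparisons. An unadjusted p under 0.05 was met by 389 genes for the IDR mutant, 211 for the interface mutant, 99 between mutants and 336 for both together. As lists, Hsf1-type chaperones stood higher in the libraries labelled IDR mutant and interface mutant (medians 0.94 and 0.87, camera adjusted p = 1.72e-10 and 3.87e-08). So did Msn2/4-type genes (0.58 and 0.56, camera adjusted p = 6.5e-05 and 3.87e-08), with no member called in either list. With an estimated correlation every list had adjusted p = 0.776 and 0.789.

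These counts depend on few libraries. With the replicate number as a block many more genes were called in each comparison, but few or none once the shallow libraries were left out. Both sets of counts are given with the processing below. For the IDR mutant edgeR called 19 genes without wild type replicate 1, 7 without IDR mutant replicate 1, 53 without IDR mutant replicate 2 and 40 without IDR mutant replicate 3. For the interface mutant it called 133 without interface mutant replicate 2, and none, YGL088W included, without wild type replicate 3 or interface mutant replicate 3. For both mutants together it called 9 without wild type replicate 1, 12, 52 and 30 without IDR mutant replicates 1 to 3, and 5 and 204 without interface mutant replicates 1 and 2. It called 1 without wild type replicate 2 or 3 or interface mutant replicate 3, where RPS22B lost its call. Between the mutants it called 28 without interface mutant replicate 1, 2 without interface mutant replicate 2 and 69 without IDR mutant replicate 3. Without the 3 libraries that lay nearer the other mutant, an alternative chosen after seeing the data, 408 genes were called for the IDR mutant (318 up, 90 down), 25 for the interface mutant and 275 between them. These counts rest on 1 library labelled IDR mutant and 2 labelled interface mutant, 1 of them with 3981 counts, and the choice by itself favors a difference between the mutants. Without the 2 shallow libraries edgeR called 0 genes in each of the 3 comparisons. The compared groups alone gave 12 for the IDR mutant and 64 for the interface mutant. On simulated data built like the nuclear IDR comparison, 94 of 100 genes changed 4-fold and 48 of 100 changed 2-fold were called, with 20.7% false calls. Without the shallow libraries these were 83 and 31, with 5.79% false calls.

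Mitochondrial transcripts were followed in the nuclear extracts. RNA was selected by its poly(A) tail, so the transcripts counted depend on that capture. They do not measure how much cytosolic mRNA the extracts hold. Their share of counts was 0.0142% ± 0.014 (SD, n = 3) in wild type, 0.0326% ± 0.0196 in the libraries labelled IDR mutant and 0.0293% ± 0.00744 in those labelled interface mutant (2-sided exact permutation p = 0.3 for each mutant, where 3 against 3 libraries allow no p below 0.1). Without the 2 shallow libraries the wild type mean was 0.0214%, and the differences from it were 0.0112 and 0.01 percentage points for the IDR and interface mutants instead of 0.0184 and 0.015. Wild type replicate 3 had 0 of 1079 counts, which allows a share of up to 0.278%, for counting error only. In starved whole cells the share was 0.0928% ± 0.0163 in wild type, 0.114% ± 0.00926 in the IDR mutant and 0.148% ± 0.0514 in the interface mutant (SD, n = 2), against 0.017% ± 0.00963 in unstressed wild type.

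Nuclear extract was compared with whole cells in starved wild type to ask which transcripts are relatively more abundant in the nucleus (n = 3 and n = 2). The glycerol transporter gene STL1 was higher in nuclear extract by 7.56 ± 0.93 (adjusted p = 9.33e-05), as were YAT1 (5.57 ± 0.81), PHM7 (4.04 ± 0.52), YHR033W (3.93 ± 0.51), the replication gene CDC6 (3.78 ± 0.52) and YOS1 (2.21 ± 0.25). Lower were HXT4 (-3.16 ± 0.44), the ribosomal protein genes RPL41A (-2.68 ± 0.37) and RPL43B (-2.32 ± 0.38), HRI1 (-2.30 ± 0.29), and the mitochondrial transcripts VAR1 (-3.90 ± 0.73), COX1 (-1.91 ± 0.38) and COX3 (-1.95 ± 0.44). The fractions were prepared as separate series of libraries, so fraction and series cannot be told apart here. The edgeR test called 1682 of 5936 genes (958 up, 724 down). On simulated data built like this comparison, 10.3% of calls were false. 57% of calls were up, against 71% with median-of-ratios factors and 79.3% with DESeq2, with which the median of all genes lay at 0.15 and 0.23.

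By list, ribosomal protein genes fell in 39 of 138 cases in both counts (median -0.62, camera adjusted p = 2.21e-11). Proteasome genes fell in 13 of 33 (17 alone, camera adjusted p = 3.7e-07), among them RPN9 at -1.38 ± 0.27 and PRE3 at -1.23 ± 0.29. Glycolysis genes fell in 9 of 17 (11 alone, camera adjusted p = 9.25e-06), among them ADH1 (-1.96 ± 0.50), TDH2 (-1.91 ± 0.45) and HXK2 (-1.80 ± 0.35). Hsf1-type chaperones fell in 9 of 22 cases in both counts (camera adjusted p = 0.000261). CPR6, YDJ1 and HSC82 stood at -1.70 ± 0.34, -1.48 ± 0.37 and -1.70 ± 0.46. The respiratory chain (1 of 32 up and 10 down, camera adjusted p = 0.00191), amino acid biosynthesis (3 of 34 up and 11 down, camera adjusted p = 0.00867) and mitochondrial transcripts (5 of 7 down, 6 alone, camera adjusted p = 0.00913) were lower too. Peroxisomal fatty acid oxidation (9 of 16 up in both counts, camera adjusted p = 1.5e-05) was higher, with PXA1 at 1.64 ± 0.38. So was gluconeogenesis (9 of 16 up, 9 up and 1 down alone, camera adjusted p = 0.000408) with ACS1, ICL1 and MLS1 at 2.63 ± 0.64, 1.67 ± 0.41 and 1.43 ± 0.31. All of these lists had adjusted p = 0.566 with an estimated correlation. Of 22 exosome and surveillance genes 5 rose and 2 fell (camera adjusted p = 0.972). The risers included NRD1 (1.55 ± 0.34), of the complex that ends transcription of short noncoding RNA. Among them too were the polyadenylating polymerase gene TRF5 (1.28 ± 0.25) and the exosome nuclease gene RRP6 (1.07 ± 0.25). NAB3, of the same complex as NRD1 but in the list of mRNA export and poly(A) binding, rose by 1.63 ± 0.35. Intron-containing genes other than ribosomal protein genes went both ways (31 of 176 up, 22 down, camera adjusted p = 0.98). DESeq2 called 150 genes, voom 2985, and the compared groups alone gave 2525. The edgeR count was 557 without nuclear wild type replicate 2, and 580 and 582 without whole cell wild type replicates in turn. Of the 29 called genes named here, 18 passed with each library left out.

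Whether a mutation changes the distribution between nuclear extract and whole cells was tested by the interaction of fraction and strain. In the libraries labelled IDR mutant the nuclear excess was smaller than in wild type for SPS100, a spore wall gene (-3.71 ± 0.45, adjusted p = 0.00118), and MLS1 (-2.12 ± 0.41, adjusted p = 0.0147). So it was for YAT1 (-4.08 ± 0.92), PDC6 (-3.81 ± 0.65), IRC15 (-3.91 ± 0.73), PCK1 (-2.64 ± 0.58), the fructose bisphosphatase gene FBP1 (-1.60 ± 0.37), CRC1 (-2.18 ± 0.43) and CAT2 (-2.02 ± 0.46). It was larger for BNA1 (2.06 ± 0.45, adjusted p = 0.024) and HRI1 (1.96 ± 0.39, adjusted p = 0.0176). SPS100, PCK1 and CRC1 are among the 114 genes over which the libraries labelled IDR mutant replicates 1 and 2 lay nearer the other mutant. YAT1, PDC6, CAT2 and CRC1 rose in the starved whole cell IDR mutant. Exchanged labels could also lower the nuclear excess of such genes. The called genes named here kept their direction without the libraries nearer the other mutant, which leaves 1 library labelled IDR mutant. Of 16 genes of gluconeogenesis 5 were more negative (10 adjusted over the list alone, camera adjusted p = 1.23e-08), and of 16 of peroxisomal fatty acid oxidation 4 (11 alone, camera adjusted p = 5.68e-09). Ribosome biogenesis (1 of 50, 8 alone, median 0.94, camera adjusted p = 9.71e-12) and ribosomal protein genes (0 of 138, median 0.67, camera adjusted p = 3.23e-14) were more positive. Each had adjusted p = 0.524 with an estimated correlation. The edgeR test called 159 of 5936 genes (39 up, 120 down), 327 without the libraries nearer the other mutant, 83 without the shallow libraries, and DESeq2 called 0. The count was 380 with the compared groups alone and 2243 with voom (1100 up, 1143 down). A block for the replicate number also raised it, with rises and falls nearer in number, as given with the processing below. Leaving out whole cell wild type replicates 1 and 2 in turn gave 3 and 1, whole cell IDR mutant replicates 26 and 12, nuclear wild type replicates 1 to 3 gave 358, 20 and 84, and nuclear IDR mutant replicates 1 to 3 gave 40, 79 and 998. In the libraries labelled interface mutant 0 genes passed by edgeR and 0 by DESeq2, with 161 at an unadjusted p under 0.05. HMS1 (1.67 ± 0.37), YDR250C (2.34 ± 0.62) and YMR173W-A (1.03 ± 0.27) had the smallest p values, each with adjusted p = 1. As lists, peroxisomal fatty acid oxidation and gluconeogenesis were more negative there (medians -0.91 and -0.85, camera adjusted p = 2.5e-12 and 7.59e-10, adjusted p = 0.495 for each with an estimated correlation). Here 65 genes passed without starved whole cell interface mutant replicate 1.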

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

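The tests that weigh explanations in this part and the counts over splits of the nuclear libraries were chosen only after the results were seen. The interaction tests were planned.

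A difference between strains in the starvation response was found in 687 genes for the IDR mutant (32 to 3209 with each library left out in turn) and in 1 gene, ADY2, for the interface mutant (0 to 3274 genes). A difference between strains in the distribution over nuclear extract and whole cells was found in 159 genes for the libraries labelled IDR mutant (1 to 998, and 0 by DESeq2). Spike-in sequences, which set the scaling only in the alternatives with spike-in factors, took 0.86%, 0.878% and 1.009% of the counts of nuclear wild type replicates 1 to 3. They took 0.608%, 0.851% and 0.717% of the libraries labelled IDR mutant, and 0.549%, 1.651% and 1.728% of those labelled interface mutant. Group means were 0.916% ± 0.0816 (SD, n = 3) in wild type, 0.725% ± 0.122 in the IDR mutant (exact permutation p = 0.1) and 1.31% ± 0.659 in the interface mutant (exact permutation p = 0.4). Here 0.1 is the smallest p that 3 against 3 libraries allow. The shares of wild type replicate 3 and interface mutant replicate 3 rest on 11 and 70 spike-in counts. Without these libraries the means were 0.869% in wild type and 1.1% in the interface mutant.

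Of the 5 mutant nuclear libraries with enough depth, 3 lay nearer the other mutant over the 114 genes that part the mutants in whole cells of both conditions. These were the library labelled interface mutant replicate 1 and those labelled IDR mutant replicates 1 and 2. A preparation shared by libraries of the same number is argued against for the library labelled interface mutant replicate 1, which among libraries of other labels correlated best with IDR mutant replicate 3 (Spearman 0.984 over genes) and at most at 0.961 with its own number; for those labelled IDR mutant it stays open, since replicate 1 correlated best with its own number (wild type, 0.984) and replicate 2 with another (0.983 against 0.962). A starvation state between the 2 measured is argued against for the library labelled interface mutant replicate 1, whose score of 1.85 lies 1.8 above the whole cells of that strain in both conditions (0.93 at most in nuclear wild type) and whose NAB2 of 119.1 CPM lies outside their range by a factor of 1.75 (1.13 at most); for those labelled IDR mutant replicates 1 and 2 it stays open, since scores of 0.60 and 0.17 lie within the whole cell range of -1.59 to 2.1 while NAB2 lies outside its own by 1.23 and 1.31. A difference between nuclear extract and whole cells in the response of a mutant, alike in all libraries of a label, is argued against as the whole cause, since scores within a label differed by 1.81 and 1.15, and by at most 0.37 within nuclear wild type and starved whole cell groups. Exchanged labels, which would need libraries out of place in both mutant groups, may account for the pattern. The same 3 libraries lay nearer the other mutant when scores were taken relative to the wild type of each fraction. Scores of 0.60 and 0.17 are also near the 0.03 and 0.40 of nuclear wild type. RPS22B, 1 of the 114 genes, did not stand near nuclear wild type. It had 88.7 and 105.7 CPM in those labelled IDR mutant replicates 1 and 2, against 359.6 and 456.3. The library labelled interface mutant replicate 1 had 38.6, and that labelled IDR mutant replicate 3 had 38.3. Means of starved whole cells were 38.2 in the IDR mutant and 96.3 in the interface mutant. But 88.7 also lies within the 34.8 to 92.6 of IDR mutant whole cells.

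Unstressed wild type replicate 1 stood apart from the other unstressed libraries, and with it the counts of the unstressed comparisons and of the interaction tests move. Gene length is part of the difference: its log2 ratio to replicate 2 fell with coding length (Spearman -0.525 over genes, -0.26 to 0.416 in the other replicate pairs), but the SD of the ratio was 0.798 before and 0.671 after the length trend was removed, above the 0.469 of the widest other pair, which argues against length as the whole cause. Cells partly starved before collection are argued against by the order of genes. Over 5253 genes the ratio correlated with the starvation effects of the IDR and interface mutants at Spearman -0.226 and -0.124. After the length trend was removed these were -0.154 and -0.068. In CPM, Msn2/4-type genes had a median ratio of -0.71 and trehalose and glycogen genes of -1.03, opposite to starvation. CPM leaves out the TMM factors of the fits, 0.799 for replicate 1 and 1.163 for replicate 2. With them every ratio would be higher by the same amount, so the sign of a list in CPM may differ from that in the fits. The correlations do not depend on this scaling. Some lists did go with starvation in CPM: ribosome biogenesis (-0.73), cyclins and DNA replication (-1.09), exosome and surveillance (-0.77), the respiratory chain (0.24) and mitochondrial transcripts (1.16). Against it in CPM went ribosomal protein (0.45), Hsf1-type (-0.7), high-affinity hexose (-1.1), glycolysis (-0.53), gluconeogenesis (-0.25), peroxisomal (-0.53), autophagy (-0.5) and cell wall genes (-1.22). A different culture stage or RNA quality was not tested.

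Of 11 features that overlap a small nucleolar RNA gene on their own strand, a group prompted by RPS22B, YGL088W (over SNR10) and YJL047C-A (over SNR60) and formed after the results were seen, 5 fell in the starved IDR mutant and 2 in the starved interface mutant, and none rose (medians -0.71 and -0.34). Of all 5853 genes, 780 fell in the IDR mutant and 4 in the interface mutant. The prompting features are counted here. RPS22B, YGL088W and YJL047C-A all fell in the IDR mutant, and RPS22B and YJL047C-A are the 2 that fell in the interface mutant. These counts thus partly restate what prompted the group. A fall of intron-containing genes in general cannot act on the 3 features without an intron. Of these, YGL088W and YJL047C-A fell in the IDR mutant and YJL047C-A in the interface mutant. Both prompted the group by falling, so their falls are no separate evidence for a pattern of the group. For the 8 with an intronic one such a fall stays open. Their median lay at percentile 70.3 of 10000 random lists of intron-containing genes in the IDR mutant and at 0.01 in the interface mutant. Reads of RPS22B assigned to its paralog are argued against, since RPS22A and RPS22B summed to 597 ± 85.7 CPM (SD, n = 2) in the starved interface mutant and 349 ± 4.85 in the IDR mutant, below the 929 ± 33.1 of wild type. Fewer polyadenylated small nucleolar RNA reads counted in the host feature could give the pattern and cannot be told apart from lower host RNA, as 2 features fell in the interface mutant and these RNAs have no feature of their own here. An effect of the mutations of Nab2, a poly(A) RNA-binding protein, stays open as untested.

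Other splits of the nuclear libraries were counted for each nuclear comparison. For the IDR mutant against wild type the real split called 1 gene, 4 of 10 splits called as many, and the highest other called 126. For the interface mutant the real split called 1, 5 of 10 called as many, and the highest other called 129. Between the mutants the real split called 0, as all 10 splits do or exceed. The highest other, IDR mutant replicates 1 and 2 with interface mutant replicate 2 against the rest, called 467. In these 3 the splits are too few for a share under 0.05. For both mutants against wild type the real split called 2, 13 of 84 splits called as many, so chance is not excluded. The highest others joined interface mutant replicate 1 and IDR mutant replicate 3 with wild type replicate 3 or with interface mutant replicate 3, and each called 709. Splits that call so many more genes than the labels do point to a structure of the libraries that the labels do not follow.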

How the results depend on the processing

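The spike-in fits, the fits without doubted libraries, the combinations with the depth limit and the list tests without unstressed wild type replicate 1 or the shallow libraries are tests chosen only after the results were seen. The other alternatives were planned. Of the called genes the text names, 165 of 172 passed with the replicate block, 150 with DESeq2, 146 of 170 tested with the compared groups alone, and 101 of the 172 with each library left out in turn. Of 330 list tests, 153 passed with camera, 9 with an estimated correlation and 96 with fry. Counts within 1.5 times those reported were given by no filter and by protein-coding genes alone in 16 of 16 comparisons, by median-of-ratios factors and a mean of 10 CPM in 15, by the replicate block in 10 and by DESeq2 in 6. Without the shallow libraries 2 wild type and 2 interface mutant nuclear libraries remain. Simulated data of that size gave 83 of 100 genes changed 4-fold and 31 of 100 changed 2-fold with 5.79% false calls. The causes of the changes below were not tested.

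With DESeq2 the count was 1352 for the unstressed IDR mutant, 100 for the unstressed and 225 for the starved interface mutant. It was 1192 and 156 for the interaction of starvation with the IDR and interface mutants, and 150 for nuclear extract against whole cells. It was 0 for the nuclear IDR mutant, the nuclear interface mutant, both together, and the interaction of fraction with the IDR mutant. With the compared groups alone it was 2473 for starvation in wild type, 0 for the unstressed and 3575 for the starved IDR mutant, and 46 for the starved interface mutant. The count was 248 and 0 for the 2 interactions with starvation, 12 and 64 for the nuclear IDR and interface mutants. It was 2525 for nuclear extract against whole cells and 380 for the interaction of fraction with the IDR mutant. With the replicate block it was 235, 174, 269 and 200 for the nuclear IDR mutant, interface mutant, the mutants against each other and both together. It was 1330 (627 up, 703 down) and 2 for the interactions of fraction with the IDR and interface mutants. Without the shallow libraries the block gave 4, 2, 0 and 2 for the nuclear IDR mutant, interface mutant, the mutants against each other and both together, and 1521 for the interaction of fraction with the IDR mutant. The labels do not say whether the replicate number pairs libraries. Residuals of libraries of the same number correlated at -0.269 to 0.602 in nuclear extracts (median 0.349, over 0.1 in 4 of 6 pairs). In whole cells they correlated at -0.428 to 0.334 (over 0.1 in 6 of 30). In a group of 2 libraries the residuals mirror each other, so these pairs are not independent. For the same reason the median of -0.344 for different numbers in nuclear extracts is no separate comparison. Pairing in nuclear extracts stays open.

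Without the nuclear libraries nearer the other mutant, a choice that by itself favors a difference between the mutants, the count was 408, 25, 275 and 127 for the nuclear IDR mutant, interface mutant, the mutants against each other and both together. It was 327 for the interaction of fraction with the IDR mutant. Without the shallow libraries it was 0 for the nuclear IDR mutant, interface mutant and both together, and 83 for the interaction of fraction with the IDR mutant. With voom it was 2, 0 and 1 for the nuclear IDR mutant, interface mutant and both together, 2985 for nuclear extract against whole cells and 2243 for the interaction of fraction with the IDR mutant. Spike-in factors gave 2 for the nuclear interface mutant and 6 for both mutants together, and 2 and 4 without the shallow libraries. With them the median of all genes lay at -0.338 for the nuclear interface mutant, -0.389 between the mutants and -0.128 for both together, against 0.003, -0.022 and 0.009 with TMM. Median-of-ratios factors gave 1 for both together. For the nuclear IDR mutant a mean of 10 CPM gave 4 and 1 fit of all libraries gave 5. With median-of-ratios factors the median of all genes lay at -0.128 for the nuclear IDR mutant, -0.186 for the interface mutant and -0.171 for both together, against 0.045, 0.003 and 0.009 with TMM. It lay at 0.15 for nuclear extract against whole cells and -0.135 for the interaction of fraction with the interface mutant, against 0.001 and -0.036.

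With each library left out in turn, counts ranged from 3136 to 4555, 3235 to 3324 and 2690 to 3188 for starvation in wild type, the IDR and the interface mutant. They were 0 to 3807 and 0 to 3655 for the unstressed IDR and interface mutants, and 796 to 991 and 0 to 288 for the starved ones. They ran from 32 to 3209 and 0 to 3274 for the interactions with starvation, and were 1 to 53, 0 to 133, 0 to 69 and 1 to 204 for the nuclear IDR mutant, interface mutant, the mutants against each other and both together. They were 557 to 1687 for nuclear extract against whole cells and 1 to 998 and 0 to 65 for the interactions of fraction. Without unstressed wild type replicate 1, 145 list tests passed. The difference of the mitochondrial share from nuclear wild type ranged from 0.0091 to 0.0286 percentage points for the IDR mutant and 0.00792 to 0.0219 for the interface mutant. NAB2, called in none of these, changed sign. It came to 0.03 for the starved interface mutant with a library left out. Between the nuclear mutants it came to 0.96 without the libraries nearer the other mutant and 0.01 without the shallow libraries. With a library left out there, it came to 0.06 and 0.15 without IDR mutant replicates 1 and 2 and 0.35 without interface mutant replicate 1. It came to 0.06 with median-of-ratios factors for nuclear extract against whole cells, and to 0.01 and 0.00 for the interaction of fraction with the interface mutant without the libraries nearer the other mutant and with a library left out.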

Other observations

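The tests on the mating-type genes and the overlap between conditions in this part were chosen only after the results were seen.

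Genes of the other mating type were higher in the starved IDR mutant. MFA1 and MFA2, which encode the a-factor pheromone of a cells, rose by 2.92 ± 0.52 (adjusted p = 0.00349) and 2.91 ± 0.35 (adjusted p = 0.000605) against starved wild type by edgeR, and STE2, the alpha-factor receptor gene of a cells, rose by 2.10 ± 0.23 (adjusted p = 0.000442). MF(ALPHA)1, the alpha-factor gene, fell (-0.84 ± 0.15). In the starved interface mutant MFA2 stood at 0.60 ± 0.39 (adjusted p = 0.668) and STE2 at 0.45 ± 0.24 (adjusted p = 0.585). MFA1 and MFA2 are among the 96 genes that stood higher in the IDR mutant than in the interface mutant, and STE2 is not. Before starvation MFA2 rose in the IDR mutant too (2.49 ± 0.47, adjusted p = 0.0356), a call that it lost with some library left out. Levels were low: MFA2 had 67 and 77 counts in the starved IDR mutant replicates, 9 and 12 in wild type and 22 and 19 in the interface mutant. In nuclear extracts MFA2 stood at 53.25 CPM in the library labelled IDR mutant replicate 3 and 31.67 in that labelled interface mutant replicate 1, against 7.314 and 3.67 in IDR mutant replicates 1 and 2, 10.92 in interface mutant replicate 2, and 3.846 and 7.397 in wild type replicates 1 and 2.

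The IDR mutant showed part of the same changes before and after starvation. Of the 66 genes higher in the unstressed mutant, 43 were also higher in the starved mutant (10.5 for unrelated calls), and of the 32 lower, 12 were also lower (4.26 for unrelated calls), among them RPS22B, YGL088W and VMA9. Another 5 genes moved in opposite ways. Changes against wild type correlated over genes between the conditions at Pearson r = 0.327 (Spearman 0.308), where genes are not independent replicates.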
